A study of Mus musculus with 9 samples.

How the data were processed

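Polyadenylated RNA was measured by strand-specific, paired-end RNA sequencing in v6.5 mouse embryonic stem cells. Per the labels' protocols, cells received KH-CB19, an inhibitor of the Clk kinases, dissolved in dimethyl sulfoxide (DMSO), or DMSO alone, and were harvested at once (0 h) or after 2 h. The 4 groups held 2 libraries each, described by the labels as independent biological replicates, so 8 libraries in all. A further untreated library, made from polyadenylated RNA by a ligation-based protocol, had no column of its own among the values used and was not analysed here.

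Per the submitters' processing notes, the tools were Bowtie 1.0.0, TopHat2 2.0.9, SAMtools 0.1.19, bedtools 2.17.0, Cufflinks 2.1.1 and DESeq, with reads placed on the mouse build mm9. The notes as used here give no settings and no order of steps. How introns were chosen and how the expected counts were made was not given in the sources used here.

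The values came from a table of introns in which the authors had already combined the 2 libraries of each group. Per the file headers, the authors gave for each intron an observed and an expected mean count at 0 h in the DMSO and the KH-CB19 group, the log2 ratio of observed to expected, and an adjusted p-value. All observed 0 h means were multiples of 0.5, as a mean of 2 unscaled counts would be, and the authors replaced the values of introns with few reads by a word for low coverage. Apart from 6 introns in each group, every intron with a value had an observed mean of at least 10. For the introns the authors classed as detained, and for no others, the table also held the authors' normalised mean read count (a signal that is not whole) in each group at 2 h, the log2 ratio of KH-CB19 to DMSO, its adjusted p-value, and a response class. The response class followed from that ratio and an adjusted p below 0.05 in every detained intron. DESeq is the only statistical tool that the authors' notes and headers name, and the adjusted p-values at 2 h and at 0 h are taken to be from it.

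Before the data were examined, the plan was a count model over the 8 libraries, with gene set tests on the same fit and each library left out in turn. It also said that, if the values were the authors' own comparisons, these would be described with no new test per intron, and this was done. No SD between replicates could be computed, since only group means were used. Also set before the data were examined were the 0.05 threshold, the 16 gene lists, the rule for named introns and the length test. So were the alternatives that treat single introns as units or add pseudocounts of 0.1, 1 and 10. A mean of at least 50 counts was set before as well, except for the list tests, as was a threshold of 0.01 for the detained class. The rule named every detained intron of Clk1 to Clk4, the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 50 counts (1 intron per gene), and up to 4 introns per list with the smallest adjusted p. For the comparison of observed with expected reads it named the 3 largest ratios in each direction past the threshold, with the same minimum. The mean behind the minimum of 50 is that of the authors' group means with a value, so it mixes unscaled 0 h and scaled 2 h means. Introns named outside this rule were chosen after their values were seen, and the text says so. Some introns that the rule would name are not reported here.

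The planned gene set tests could not be made on group means. They were replaced, after the table and the number of changed introns in each list had been seen, by Fisher's exact test (two-sided) across genes with a detained intron. It compared the share of list genes with an intron that rose, fell or did either with the share among all other such genes. Lists with at least 3 such genes were tested, and Benjamini-Hochberg adjustment covered all lists and directions together. Genes are not independent replicates, so these p-values describe how calls are spread over genes and not the spread between cultures. As genes with more detained introns or more reads have more chances of a call, 10000 random lists matched on both were also drawn, giving one-sided permutation p-values adjusted over the lists within each direction. For counts adjusted over the list alone, the unadjusted p was recovered from the authors' adjusted p. The same was done for adjusting again over introns of at least 50 reads and for the count without adjustment. This assumes Benjamini-Hochberg adjustment over all 3454 detained introns and gives the exact value or an upper bound. Intron lengths were compared by two-sided permutation tests with 100000 resamples. The number of genes whose changed introns all went one way was compared with 10000 permutations of the calls (one-sided), a test also chosen after the data were seen. The code of the list test was tested on simulated data: a list of 30 genes with 8 planted falls was called in 20 of 20 rounds, and 0 of 300 lists without planted falls were called. This shows only that the code finds a planted excess, since the planted share is large and the simulated calls had no link to read count.

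For the 0 h groups, and for 2 h against 0 h, ratios of the authors' group means were formed and centred on the median detained intron. The 0 h means are unscaled and the 2 h means scaled, and both times were normalised separately, so these ratios have no test. Within genes with at least 4 introns, the expected count rose with intron length (slope 0.60 of log2 expected count on log2 length, r = 0.93 across introns, which are not independent). The log2 ratio of expected counts between the KH-CB19 and DMSO groups was examined in a subset of 4324 of the 22228 introns. Its SD there was 0.0044 within genes against 0.20 over the whole subset. A gene with only 1 intron in the subset would add no spread, which would lower the SD within genes. Within this subset the ratio of expected counts was close to 1 value per gene, and other introns were not examined for this. The ratio is not read as a measure of the transcript, since what the expected counts were made from was not given.

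Intron positions are those of the deposited table on mm9, whose starts count from 0, and are printed counting from 1. No annotation of that build was used. Introns were matched by gene symbol and exact length to introns of GENCODE M21, which is on a later build, and 19067 of 22228 (85.8%) matched exactly 1 intron, against 102 when 1 base was added to each length. Only the annotation of the matched intron was taken, and no coordinate was converted. Intron numbers are those of the deposited table.

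Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. A read count in an intron at 2 h changes with splicing, with RNA decay and with the amount of the transcript, and the table held no value at 2 h for other introns or for exons that would separate them.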

Results

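The data are read counts in introns of polyadenylated RNA from v6.5 cells, a mouse embryonic stem cell line, which received KH-CB19, an inhibitor of Clk kinases, or its solvent DMSO. Clk kinases phosphorylate SR proteins, a family of splicing factors rich in arginine and serine. Cells were harvested at 0 h or 2 h, with 2 libraries in each of the 4 groups. All values are the authors' group means, ratios and adjusted p-values, so no spread between replicates stands beside them. The authors' deposited table covered 22228 introns of 7016 genes. The authors' deposited table had an observed 0 h mean for 21568 introns in the DMSO group, which summed to 1286589 reads, and for 18740 introns in the KH-CB19 group, which summed to 1002850 reads. Over detained introns alone, the normalised means in the authors' deposited table summed to 369104 reads in DMSO and 392295 reads in KH-CB19 at 2 h. Depth of whole libraries is not known from these sums. RNA integrity numbers of the 8 libraries were between 8.8 and 9.4, and the lowest belonged to replicate 2 of the KH-CB19 group at 2 h.

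The first question was which introns held more reads than the authors' expected counts. Detained introns, the series' name for introns that stay in polyadenylated RNA and are spliced later, numbered 3454 in the authors' deposited table (15.5% of introns) and lay in 2427 genes (34.6%). Of these genes, 1676 had 1 detained intron, 549 had 2, 142 had 3 and 60 had at least 4, and Spna2, which encodes a spectrin, had the most, with 6. Intron 6 of Ogt, the gene of the O-GlcNAc transferase, was among the detained introns, at chromosome X from 98847548 to 98850962 on mm9 and between coding exons. The authors' deposited table gave it 623.5 observed and 72.5 expected reads in the DMSO group at 0 h, a log2 ratio of 3.10, and a log2 ratio of 3.16 in the KH-CB19 group. Intron 5 of Clk1 had 579.0 observed and 199.5 expected reads in DMSO at 0 h in the authors' deposited table (log2 ratio 1.54).

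In the authors' deposited table, 3408 of 3453 detained introns with a DMSO value at 0 h were above expectation at adjusted p below 0.05, with a median of 3.56-fold over all 3453. In the KH-CB19 group at 0 h, 3207 of 3423 were above, with a median of 3.52-fold in the authors' deposited table. Both groups were past the threshold for 3162 detained introns and neither for 1, intron 6 of Clk4. No detained intron was below expectation past the threshold in either group. The rule behind the class was not given. If it drew on these same ratios, the excess follows from the class and is no separate support for it. Among the other introns of the authors' deposited table, 2678 were above and 2350 below expectation in DMSO, with a median of 1.23-fold. The largest ratios past the threshold in the authors' deposited table belonged to intron 6 of Nup93 (10653.5 observed and 0.5 expected reads in DMSO) and intron 3 of Slc25a5 (3882.0 and 0.5), neither classed as detained, and to intron 3 of Dppa5a (2571.0 and 0.5), which was. An expected mean of 0.5 is the smallest above 0 that these means can take, so the size and rank of these ratios rest on an expected count at its floor. The lowest in DMSO were intron 19 of Hsp90ab1 (98.0 observed and 3518.5 expected reads), intron 5 of Actb (79.5 and 2037.0) and intron 17 of Zfp57 (59.5 and 1293.5) in the authors' deposited table. Actb, Hsp90ab1 and Slc25a5 have near-identical copies elsewhere in the genome, and how shared reads were counted was not given in the sources used here, so their values are uncertain. Detained introns had a median length of 1562 bp against 2044 bp for the others. Of the 2802 detained introns matched to the annotation, 94.7% lay between coding exons, 1.57% in 5′ UTRs and 1.78% in 3′ UTRs.

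The main comparison asked which detained introns changed after 2 h of Clk inhibition. The largest falls among introns with a mean of at least 50 reads over the 4 groups were in Clk1 and Clk4, which encode kinases that the compound inhibits. Intron 5 of Clk1 (chromosome 1, 58477056 to 58477926, between coding exons) went from a mean of 493 normalised reads in DMSO to 41.6 in KH-CB19 in the authors' deposited table, 11.8-fold lower (log2 ratio −3.56, adjusted p = 4.02e-44). Intron 7 of Clk1 (chromosome 1, 58476578 to 58476964) was 10.8-fold lower in the authors' deposited table (adjusted p = 5.21e-24), and intron 11 of Clk1 (chromosome 1, 58471529 to 58473856) was 1.72-fold lower (adjusted p = 0.00234). All 3 detained introns of Clk4 fell: the authors' deposited table gave log2 ratios of −2.87 for intron 10 (adjusted p = 4.8e-11), −2.76 for intron 7 (adjusted p = 2.06e-18) and −1.65 for intron 6 (adjusted p = 0.00225). These lie on chromosome 11, at 51086671 to 51087061, 51085525 to 51086579 and 51084098 to 51085301, all between coding exons. The detained introns of Clk2 and Clk3 did not pass: log2 ratios in the authors' deposited table were −0.64 and 0.11 for introns 4 and 7 of Clk2 (adjusted p = 0.311 and 0.978) and 0.44 for intron 3 of Clk3 (adjusted p = 0.293). Whether the introns of Clk2 and Clk3 differ from those of Clk1 and Clk4 was not tested. The other introns of these genes had no 2 h value, so how much of each fall belongs to the amount of the transcript was not measured; within Clk1 the falls were unequal.

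**Figure D1:**
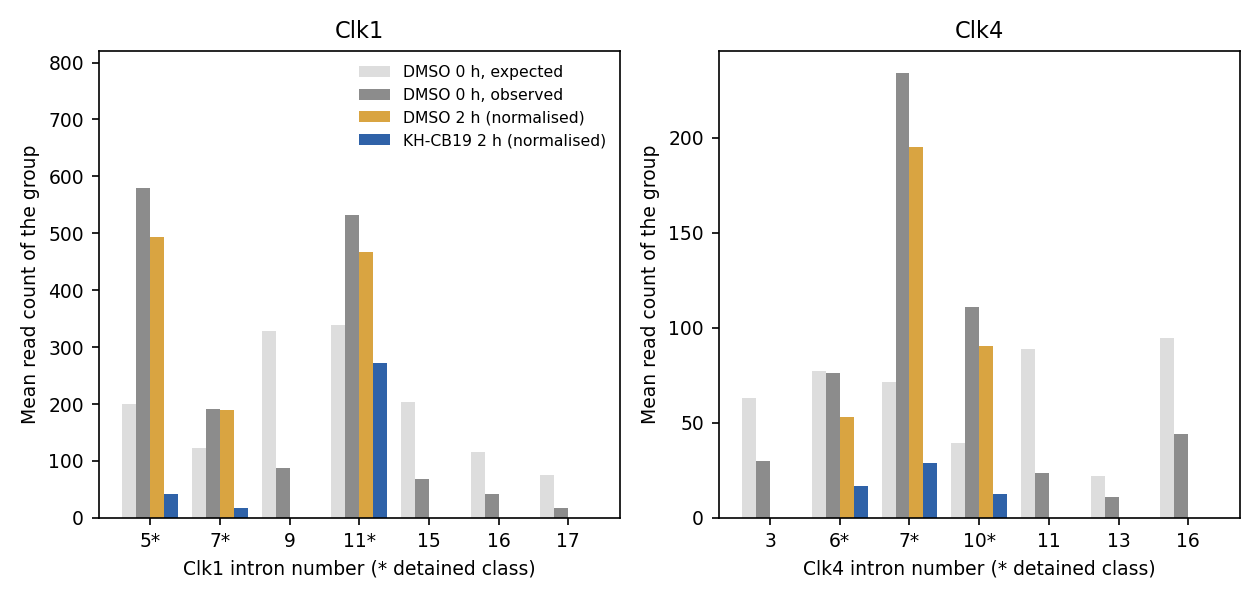
Mean read counts per intron of Clk1 (left) and Clk4 (right), from the authors' deposited table; bars show expected and observed reads in DMSO at 0 h and normalised reads at 2 h in DMSO and KH-CB19, with no error bars because only group means were used. Introns marked with an asterisk are in the detained class, and the others have no 2 h bars because they have no 2 h value; Clk1 intron 5 stands at 493 in DMSO and 41.6 in KH-CB19 at 2 h.

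Across all detained introns, 333 (9.64%) in 300 genes changed at adjusted p below 0.05 in the authors' deposited table. In 170 genes, 189 introns rose, with a median of 2.15-fold (quartiles of the log2 ratio 0.87 and 1.34). In 131 genes, 144 introns fell, to a median of 0.448 of the DMSO level (quartiles of the log2 ratio −1.50 and −0.92). The remaining 3121 did not pass, and the median log2 ratio of all 3454 was 0.00 with an SD of 0.60 across introns. The authors' response class reads "Less" for all introns that rose and "More" for all that fell. Changed introns in the same gene mostly moved in 1 direction: of 28 genes with at least 2 of them, 27 had all in 1 direction, against a mean of 13.1 and a highest of 23 over 10000 permutations of the calls (permutation p = 1e-04, the smallest these permutations can give). Introns 9 and 10 of H2afy, a histone gene named after its values were seen, overlap and share reads, and with 1 of them left out 26 of 27 genes had 1 direction (permutation p = 1e-04, again the smallest possible). The exception, also named after its values were seen, was Mybl2, a transcription factor of the cell cycle. With the unadjusted p recovered from the authors' adjusted p, at least 724 detained introns lay below 0.05 without adjustment.

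**Figure D2:**
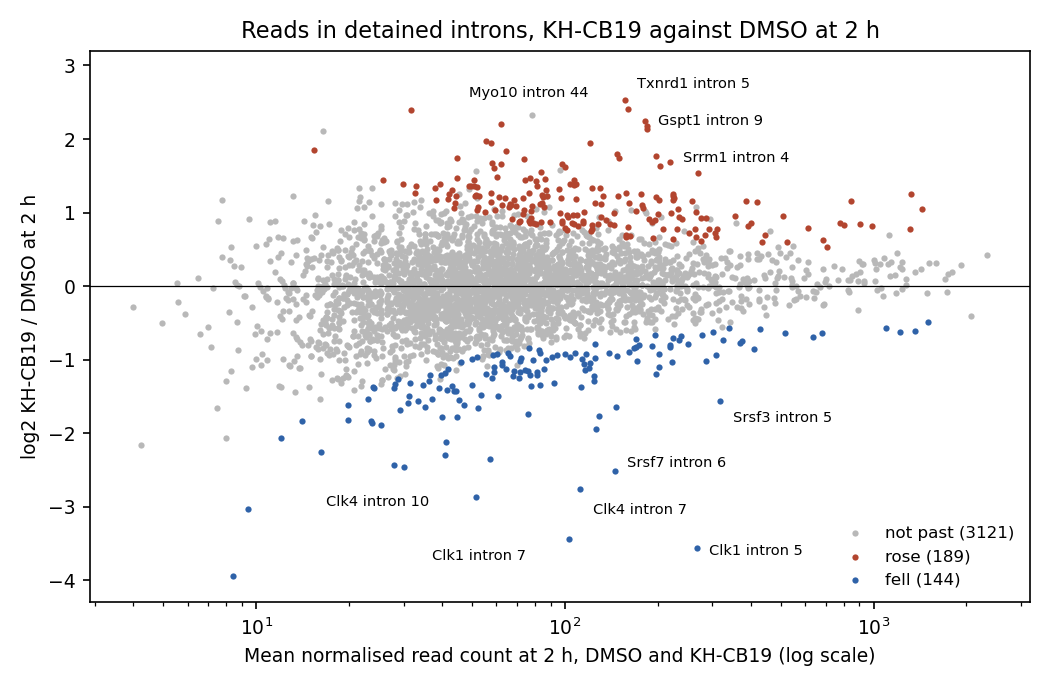
Log2 ratio of KH-CB19 to DMSO at 2 h (vertical axis) against the mean normalised read count of the 2 groups (horizontal axis, log scale) for each of the 3454 detained introns of the authors' deposited table. Each point is an intron, coloured by whether it rose (189), fell (144) or did not pass adjusted p below 0.05 (3121). The labelled introns of Clk1, Clk4, Srsf7 and Srsf3 are all among the falls.

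After Clk1 and Clk4, the largest falls among introns with a mean of at least 50 reads over the 4 groups came from genes of several kinds. Intron 6 of Srsf7, which encodes an SR protein, was 5.73-fold lower in the authors' deposited table (247 to 43.1 normalised reads, adjusted p = 2.06e-18; chromosome 17, 80604422 to 80604601, between coding exons). Intron 17 of Ncapg, a condensin subunit, fell with a log2 ratio of −2.47 in the authors' deposited table, and intron 94 of Macf1, a linker of microtubules and actin, with −2.34. Ptprf, a receptor tyrosine phosphatase, had a log2 ratio of −2.29 in intron 11, and Clcn3, a chloride transporter, of −2.12 in its intron 11 in the authors' deposited table. The same list of falls in the authors' deposited table held intron 8 of Mtpap, the mitochondrial poly(A) polymerase (−1.94), intron 4 of Mapre1, which binds microtubule ends (−1.78), and intron 16 of 4930447C04Rik (−1.78).

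Among introns with a mean of at least 50 reads over the 4 groups, the largest rises were smaller in fold than the falls of introns 5 and 7 of Clk1. Intron 5 of Txnrd1, a thioredoxin reductase, went from 46.2 to 266 normalised reads in the authors' deposited table, 5.76-fold higher (adjusted p = 0.000914; chromosome 10, 82335758 to 82337357, not matched to the annotation). Intron 44 of Myo10, an unconventional myosin, was 5.29-fold higher in the authors' deposited table (adjusted p = 2.06e-18; chromosome 15, 25737944 to 25740113, between coding exons), and intron 9 of Gspt1, a translation termination factor, 4.73-fold higher (adjusted p = 1.41e-17). Sec24b, a COPII coat protein, rose 4.52-fold in intron 3 and Nsun2, an RNA methyltransferase, 4.38-fold in intron 10 of the authors' deposited table. The rises in the authors' deposited table also held a pair of nuclear pore genes, Nup133 (intron 16, 3.85-fold) and Tpr (intron 59, 3.47-fold). Intron 16 of Ppp2r5c, a subunit of protein phosphatase 2A, was 3.59-fold higher in the authors' deposited table, intron 20 of Phc1, a Polycomb protein, 3.42-fold, and intron 18 of Hells, a chromatin remodeller, 3.36-fold. Of the rises named in this paragraph, that of Txnrd1 had the largest adjusted p, although its fold was the highest.

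Of the 26 genes for SR and SR-related splicing proteins with a detained intron, 7 had an intron that fell and 4 one that rose. Srsf7 fell as above, and intron 9 of Srsf5 (log2 ratio −1.76, adjusted p = 2.43e-09) and intron 5 of Srsf3 (−1.56, adjusted p = 1.52e-11) fell in the authors' deposited table, while intron 4 of Srrm1, a splicing coactivator, rose (1.69, adjusted p = 1.62e-11). The share of genes with a fall was 26.9% against 5.16% of the other genes with a detained intron (odds ratio 6.77, adjusted p = 0.00616, Fisher's exact test), and 11 of 26 changed in either direction (odds ratio 5.36, adjusted p = 0.00465). By introns, 9 of 47 fell and 4 rose over all detained introns, and 10 fell and 4 rose adjusted over the list alone. Against random lists matched on number of detained introns and reads, which held 2.44 genes with a fall on average, the fall count had an adjusted p of 0.0832 and the count of either direction one of 0.289 (one-sided permutation), so both calls ended there. The median log2 ratio of the 26 genes was −0.15, at percentile 0.23 of those random lists, whose central 95% ran from −0.08 to 0.23. At 0 h the genes of this list already had a low ratio of expected counts in KH-CB19 to DMSO (median centred log2 ratio −0.14).

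Among hnRNP proteins, which bind nascent RNA, 5 of 19 genes had an intron that fell and 2 one that rose. Intron 24 of Hnrnpm (log2 ratio −0.98) fell in the authors' deposited table, and intron 4 of Hnrnpu (0.86) and intron 12 of Taf15 (0.77) rose. The share with a fall was 26.3% against 5.23% outside the list (odds ratio 6.47, adjusted p = 0.0348, Fisher's exact test). Matched random lists held 1.78 genes with a fall on average, and against them that call ended with adjusted p = 0.143 (one-sided permutation). It also ended with 0.106 for introns of at least 50 reads and 0.689 at a threshold of 0.01 (Fisher's exact test). The median log2 ratio of the 19 genes was 0.04, at percentile 31.4 of those random lists. By introns, 7 of 32 fell and 2 rose, and 7 fell and 5 rose adjusted over the list alone. Of the 6 genes for CLK, SRPK and DYRK kinases with a detained intron, 2 had a fall, Clk1 and Clk4 (adjusted p = 0.293, Fisher's exact test across genes). Counted by intron, 6 of their 11 fell and 0 rose (adjusted p = 8.29e-05, Fisher's exact test across introns, which are not independent), and 6 fell and 1 rose adjusted over the list alone. The median log2 ratio of the 6 genes was 0.09, at percentile 62.7 of matched random lists. Intron 14 of Srpk1, an SR protein kinase, had a log2 ratio of 0.51 in the authors' deposited table (adjusted p = 0.104).

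None of the tests of the other groups for RNA processing passed. In the core spliceosome, 3 of 54 introns rose and 0 fell: intron 28 of Dhx38, an RNA helicase (1.31), intron 16 of Prpf3 (1.03) and intron 16 of Cdc5l (0.78) had these log2 ratios in the authors' deposited table. Fisher's exact test gave an adjusted p of 0.839 for the falls and of 1 for the rises. Among cleavage and polyadenylation factors 4 of 20 introns rose, in Cstf3 (intron 15, 1.44), Wdr33 (intron 17, 1.37) and Cpsf6 (intron 5, 1.22) in the authors' deposited table, and 1 fell, intron 15 of Zc3h14 (−1.15). The 3 of 14 genes with a rise gave an adjusted p of 0.409 (Fisher's exact test). In other RNA-binding splicing regulators 4 of 45 introns fell, in Rbm25, Elavl1 and Rbm5 (log2 ratios of −1.66, −1.36 and −0.72 for introns 27, 7 and 8 in the authors' deposited table), and intron 20 of Rbm6 rose (1.14). Adjusted over the list alone, 4 of these fell and 2 rose. Of 29 introns in genes for nonsense-mediated decay and nuclear RNA surveillance, 1 fell, intron 6 of Zcchc7 (−1.19 in the authors' deposited table).

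Of 58 introns of chromatin regulators 4 rose, among them intron 21 of the histone demethylase gene Kdm3a (log2 ratio 2.20 in the authors' deposited table) and intron 6 of Eed, a Polycomb protein (1.18), and 2 fell, among them intron 47 of Ep400 (−1.43). In the DNA damage response and p53 pathway 1 of 45 rose, intron 25 of Xrcc5 (1.19), and 1 fell, intron 7 of the p53 regulator Mdm4 (−0.64), in the authors' deposited table. Cell cycle and apoptosis genes had 2 rises, in Ccnk (intron 8, 1.25) and Cdc25a (intron 12, 0.92), and 1 fall, in Ccnt2 (intron 5, −0.73), among 22 introns of the authors' deposited table. Ribosomal proteins and translation factors had 3 rises and 0 falls among 21 introns, and among the rises intron 15 of Eif3b had a log2 ratio of 1.67 and intron 7 of Rpl7 of 0.67 in the authors' deposited table. In the pluripotency network 1 of 15 rose, intron 16 of Tfcp2l1 (0.77 in the authors' deposited table), and 0 fell. None of the 3 detained introns in immediate-early and stress genes (Hsp90aa1, Hspa8 and Hsph1) passed, with log2 ratios of −0.44, 0.30 and 0.19 in the authors' deposited table. No test of these groups passed either; the smallest adjusted p was 0.409, for the rises in ribosomal proteins and translation factors. Adjusted over the list alone, the counts were the same for these groups, the core spliceosome, cleavage and polyadenylation factors and nonsense-mediated decay genes. Rpl7 has near-identical copies elsewhere in the genome, which makes its value uncertain.

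Of the O-GlcNAc cycling genes, intron 10 of Mgea5, the O-GlcNAcase gene, rose (log2 ratio 0.73, adjusted p = 0.0235 in the authors' deposited table), and intron 6 of Ogt had a log2 ratio of 0.13 (adjusted p = 0.788). Markers of other cell types were scarce. Of 27 markers of germ layers and trophoblast 3 had an intron in the table and 0 a detained intron, and of 16 fibroblast markers only Fn1 did, with 5 detained introns, of which intron 34 fell (log2 ratio −1.01 in the authors' deposited table). These lists had too few genes for a test.

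**Figure D3:**
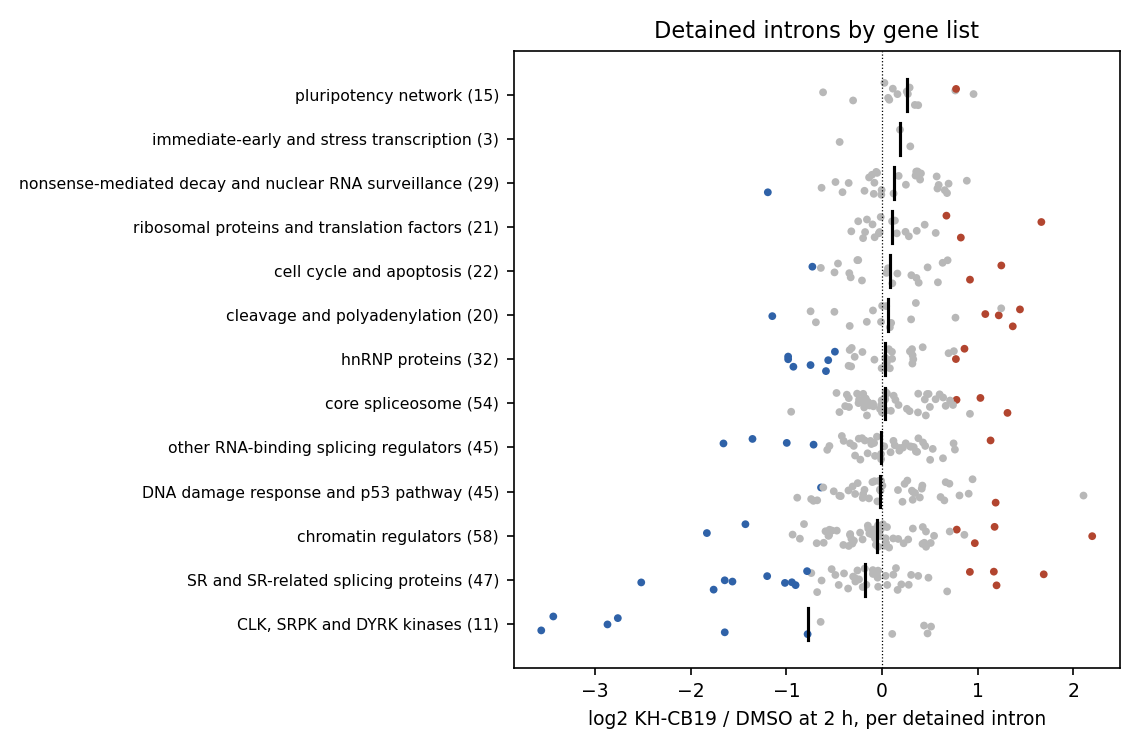
Log2 ratio of KH-CB19 to DMSO at 2 h for each detained intron (points) in the gene lists with at least 3 genes that have a detained intron, from the authors' deposited table; the number of introns is in parentheses and the black bar is their median. Red points rose, blue points fell and grey points did not pass adjusted p below 0.05; the 4 points furthest to the left are introns of Clk1 and Clk4, followed by intron 6 of Srsf7.

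The 0 h groups give the background of the treatment comparison. In cells harvested at once, the introns called as risen or fallen at 2 h lay near the other detained introns: their median log2 ratios of KH-CB19 to DMSO at 0 h, centred on all detained introns, were −0.04 and −0.06 in the authors' deposited table. The 6 detained introns of Clk1 and Clk4 all had a centred ratio below 0 at 0 h in the authors' deposited table: −0.30, −0.40 and −0.10 for introns 5, 7 and 11 of Clk1, and −0.27, −0.27 and −0.46 for introns 6, 7 and 10 of Clk4. Over 3422 detained introns the SD of the ratio across introns was 0.30 at 0 h and 0.60 at 2 h, and 23 against 309 introns lay at least 2-fold from the median. The ratios at the different times showed little relation across introns (r = 0.02, rho = 0.01; introns are not independent). These group ratios have no test, and the 0 h means are unscaled.

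Set against 0 h, the median change of the called introns was larger in the KH-CB19 group, though single introns could differ. Introns that rose had a median centred log2 ratio of 2 h to 0 h of −0.15 in DMSO and 1.02 in KH-CB19, and introns that fell of 0.10 and −0.99, from the means in the authors' deposited table. These introns were called on the ratio of KH-CB19 to DMSO at 2 h, so a gap between the treatments follows largely from the call. Which treatment held the larger change was not fixed by it. In DMSO 20 detained introns lay at least 2-fold from the median and in KH-CB19 320. The times were normalised separately, so neither the time course nor its difference between treatments was tested.

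Changed introns were long for their class. Introns that rose had a median length of 2087 bp and introns that fell of 2309.5 bp, against 1503 bp for detained introns that did not pass (ratios 1.39 and 1.54, adjusted p = 0.000495 and 0.00027, permutation tests). Rises and falls did not differ past the threshold (permutation p = 0.353). With introns of at least 50 reads, the ratio was 1.11 for rises (adjusted p = 0.258) and 1.42 for falls (adjusted p = 0.00435) by permutation, so the call for rises ended.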

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

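The alternatives at thresholds of 0.01 and 0.1 for changed introns, and of 0.01 for gene lists, were chosen after seeing the data. So were those at 2-fold, with equal totals, with matched lists, without Clk1 and Clk4, and with at least 50 reads in the list tests. The threshold of 0.01 for the detained class was set before. No paired analysis was possible because only group means were used. For the same reason other normalisations, count models, gene set tests on the libraries and leaving out each replicate were not run. At an adjusted p below 0.01 the 333 changed introns became 217 (124 rises and 93 falls), and at 2-fold or more 207 (114 rises and 93 falls), by construction of the stricter limits. With introns as units 6 list tests passed in place of 3, among them hnRNP genes changed in either direction; introns of a gene are not independent. With introns of at least 50 reads, the length ratio of rises was 1.11 (permutation, adjusted p = 0.258). Matching on read count also gave a drop but cannot decide, since the mean it used contains the change itself (other observations). Without Clk1 and Clk4 the odds ratio for falls in the kinase list was 0, by construction, since they held all its falls. The matched lists that ended the calls for SR and hnRNP genes, and the limits that ended the hnRNP call, stand in the report. The SR falls passed those limits, with adjusted p = 0.0233 for at least 50 reads and 0.00395 at a threshold of 0.01 (Fisher's exact test). Adjusting again over the 2118 introns with at least 50 reads gave 296 changed introns, with 272 of 272 kept and 24 added, and a threshold of 0.1 gave 451. Calls were a larger share of the 2118 than of all detained introns, so none of the 272 could be lost. Scaling to equal reads in detained introns lowered log2 ratios by 0.088, which is too little to turn a called intron, and moved the introns above 0 from 1722 (49.9%) to 1474 (42.7%). Pseudocounts of 0.1, 1 and 10 left 207, 204 and 151 called introns at 2-fold or more. The class had 2662 introns above expectation in both groups at 0.01, in place of 3162, and the rule behind the class may fix such counts in part. Of 71 named introns with at least 50 reads, 71 stayed on their side of the threshold, where those past it had to stay for the same reason. Depth limits the low end: detained introns had a median of 57.9 reads in DMSO at 2 h.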

Other observations

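The tests of class membership and of the 0 h ratio by gene list, the comparison of introns spanned by an exon, the tests on other detained introns of a gene, and the length tests within groups of read count were chosen after the results were seen. Apart from the treatment, membership of the detained class was uneven across gene groups. Of 58 measured chromatin regulators 40 had a detained intron, among them Kdm3a, Eed and Ep400, against 31.0 on average in 10000 random lists matched on introns in the table and expected reads (one-sided permutation, adjusted p = 0.0289). Of 42 measured genes of the DNA damage response and p53 pathway 29 did, against 21.9 (permutation, adjusted p = 0.0289), and of 20 cleavage and polyadenylation genes 14 did, against 9.11 (permutation, adjusted p = 0.0289). For SR and SR-related proteins the count was 26 of 36, against 22.0 (permutation, adjusted p = 0.171), and for the pluripotency network 10 of 27, against 8.50 (permutation, adjusted p = 0.533). Ribosomal proteins and translation factors lay on the other side, with 15 of 36 against 21.4 (one-sided permutation p for an excess 0.996). The matching used broad classes of both properties, with all genes of many introns in a single class. Genes with more introns could therefore still have more chances of a detained intron than the random lists.

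Several gene lists had a low ratio of expected counts in KH-CB19 to DMSO at 0 h. The median centred log2 ratio of expected counts, KH-CB19 to DMSO, was −0.14 for SR and SR-related genes and −0.15 for hnRNP genes, at percentiles 0.08 and 0.05 of 10000 random lists, and −0.15 for cleavage and polyadenylation genes, at percentile 0.46. Other RNA-binding splicing regulators (−0.10, percentile 1.3), the core spliceosome (−0.08, percentile 1.51) and the DNA damage response and p53 pathway (−0.09, percentile 2.15) were also low, so this was not limited to splicing factors. Intron 5 of Clk1 had a value of −0.25 and intron 7 of Clk4 one of −0.35. These are ratios of 2 group means with no replicate check. Of 2801 detained introns, 17.1% were spanned by an annotated exon of the same strand, against 12.2% of other introns matched on length and reads (permutation p = 0.001, the smallest that 1000 permutations can give).

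The first pattern weighed is the change of detained introns at 2 h. If the reads of the whole host gene had moved, its other detained introns would have moved as far. In 31 genes with a strong call and a further detained intron of at least 50 reads, the others' log2 change was set against that of the called intron. The median ratio was 0.0613 (95% bootstrap interval −0.0385 to 0.376). The called intron was the one with the smallest adjusted p of its gene, below 0.0001. This choice alone lowers the ratio by an amount that was not measured, so the ratio cannot decide against a change of the whole gene. The others moved in the same direction in 18 of the 31 genes, with ratios of 0.76 in Atp5c1 (named after its values were seen), 0.75 in Cstf3, 0.65 in Srsf7 and 0.59 in Clk1, and little or the other way in genes such as Srrm1, Tpr, Phc1 and Macf1. Clk4 was the 1 gene with a ratio of at least 0.8 (1.04). A change of the whole transcript stays open there and, as at least a part of the change, elsewhere. An effect of the inhibitor on splicing of single introns is a hypothesis that stays open, since no exon values at 2 h were used.

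The next pattern is the greater length of changed introns. Longer introns hold more reads and so may pass the test more easily. Introns were placed in 10 groups by their mean read count over DMSO and KH-CB19 at 2 h. Within these, the length ratio of rises to introns that did not pass went from 1.39 to 1.07 (permutation p = 0.424). The ratio for falls went from 1.54 to 1.46 (permutation p = 0.0004). That mean contains the change itself, which moves rises up and falls down among the groups. The test therefore cannot decide whether read count explains either length difference. No biological explanation was tested.

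The last pattern is that 583 introns at least 2-fold above expectation at adjusted p below 0.01 in both 0 h groups are not in the detained class, among them intron 6 of Nup93 and intron 3 of Slc25a5. Exons of other transcripts inside such introns could add reads and lead to their exclusion. Of the 459 matched to the annotation, 51.9% held an exon edge of the same strand, against 59.8% of length-matched detained introns. The difference was −7.96 percentage points (permutation p = 0.0121). Any such exon was counted, also one that reaches in from a transcript of the same gene. Exons that span a whole intron were not counted as edges, and the annotation was of a later build. The share was below that of detained introns, where this explanation needs it above. This argues against annotated exon edges, counted in this way, as what sets the 459 introns apart. Exons of other genes were not counted apart from those of the same gene, so a part played by them stays open. Their median length was 5777 bp, and the rule that left them out of the class stays open. No biological explanation was tested.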
